A study of Homo sapiens with 12 samples.

How the data were processed

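The samples were CHP134 cells, an established human neuroblastoma cell line, exposed for 90 min to vehicle or to 5 µM of a compound that the labels call CPX and describe as an iron chelator. Total RNA and polysomal RNA were hybridised to separate one-colour Agilent human expression arrays. This gave 4 groups (vehicle total, CPX total, vehicle polysomal, CPX polysomal) of 3 arrays each, 12 in all. Sample titles call the control untreated, while the protocol and compound labels call it vehicle, and vehicle is the word used here. Per the labels' protocols, polysomal RNA came from lysates of cycloheximide-treated cells spun through a sucrose gradient and was extracted with proteinase K and phenol-chloroform, whereas total RNA was purified on columns. RNA fraction and extraction procedure therefore cannot be told apart. The labels also say that the experiment was repeated from cell seeding for each replicate number.

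The deposited scanner tables, a file for each array, hold spot intensity on a linear scale. Per the file headers, Agilent Feature Extraction 10.7.3.1 measured each spot, subtracted background and wrote the processed intensity, while the submitters' processing notes name version 10.7.7.1 of the same program. The deposited series matrix holds log2 values whose normalization is not given in the sources used here. Each of its 12 columns matched its own array best (r of at least 0.999 with the log2 processed intensity across probes), and the column medians lay between 7.37 and 7.40, so the scale is log2 and the direction is the same. Its centring stays unknown. Those values served as an alternative. No column of a sample outside the series was present. The genome build named in the file headers is GRCh37, and probe coordinates are given on it.

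Each array held 45015 spots, of which 1639 were controls and were left out. The remaining 43376 spots carry 41000 probes, and spots flagged as outliers by the image software, between 67 and 136 per array, were dropped. No spot was saturated. Spots of 1 probe were averaged, log2 processed intensity was taken, and each array's 75th percentile (a linear signal of 1757 to 3076) was subtracted. A probe was kept if well above background on all 3 arrays of at least 1 group. Of different probes for 1 of the 29429 gene names, the brightest over all 12 arrays was used. Disagreements in sign between probes are stated where a gene named by the rule below appears in a CPX comparison. Probes were not compared for polysomal against total RNA in vehicle or for the averaged effect. Nor were they for list members named only because they passed adjusted over the list alone. Of the genes that passed, 6 with fewer than the needed values in a group were left out and 44 were tested with a missing value, which left 19251. Names were updated through a RefSeq gene table of assembly GRCh38.p14, used for names only: 27294 probes matched by accession, 2383 by symbol and 454 by synonym, and 10869 kept the file's name. Of the genes tested, 14296 had a current symbol and 4955 were known only by an accession, clone or LOC number. Where a probe was not well above background on any array of a group, the fold is a bound, written "at least N-fold": the brighter group's mean against, per array, the higher of the dim probe's own signal and the lowest signal among probes well above background.

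All tests used limma 3.58.1 in R 4.3.3 with data.table (version 1.17.8). A fit of 4 group means over all 12 arrays (8 residual degrees of freedom) gave CPX against vehicle in total RNA, the same in polysomal RNA, the difference between these effects (the interaction), and polysomal against total RNA in vehicle. Tests were two-sided and moderated with eBayes, and p-values were adjusted by Benjamini-Hochberg over all genes, with 0.05 as the threshold and no minimum fold. Standard errors of gene effects are those of the fit, so they pool the spread of all groups, and standard errors of list medians are taken over genes. The median SD was 0.10 and 0.13 in the total RNA groups and 0.19 in both polysomal groups. For a typical gene, pooling therefore widens errors and intervals in total RNA and narrows them in polysomal RNA. Numbers of calls in the 2 fractions depend in part on this. A rank or permutation test of 3 arrays against 3 cannot go below 0.1, which is why moderated tests were used. Because levels are relative to each array's own 75th percentile, a change shared by all polysomal RNA is not visible.

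There were 28 gene lists: HIF-induced genes, glycolysis and glucose uptake, iron uptake, storage and iron-sulfur genes, iron- and oxoglutarate-dependent dioxygenases, ATF4 and integrated stress response, p53 targets, immediate early genes, cytosolic ribosomal proteins, other 5' TOP mRNAs, translation initiation factors, polyamine metabolism and eIF5A hydroxylation, ribosome biogenesis, MYCN and MYC-family targets, G1/S and DNA replication, G2/M, replication-dependent histones, nuclear-encoded OXPHOS subunits, mitochondrially encoded transcripts, cholesterol synthesis, heat shock proteins, ER unfolded protein response, NRF2 targets, metallothioneins and zinc transporters, BCL2 family, proteasome subunits, adrenergic neuroblastoma identity, mesenchymal or Schwann-like cell markers, and nuclear or non-coding RNAs. Lists can share genes: 9 of the 37 measured HIF-induced genes, for example, also stand in another list. A list with at least 5 measured members was tested with camera, which compares its genes with all others, at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The fry test, which asks whether a list's genes move on balance one way without comparing them with other genes, was run beside it. List p-values were adjusted over the lists within a comparison.

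Lists, tests, the alternatives and the rule for named genes were fixed before the data were examined, except that leaving out arrays in the list tests, the HIF list without ADM and the CPX effect averaged over both fractions were added later, as were 3 further lists (ER translocon and glycosylation machinery, genes named ZNF or ZFP, and clock genes) that results had prompted. The rule named, first, in each CPX comparison the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a symbol and with non-overlapping arrays, 5 and 5 for polysomal against total RNA, or, where none passed, the 5 rising and 5 falling genes with the smallest p. Second, it named 25 genes in every CPX comparison, among them TFRC, FTH1, FTL, HIF1A, VEGFA, ADM, BNIP3, EGLN1, EGLN3, CA9, DDIT4, NDRG1, KDM3A, SLC2A1, MYCN, MYC, RRM2, ATF4, DDIT3, CDKN1A, EIF5A, DOHH, DHPS and ODC1. Last, for each list described it named up to 4 members past the threshold, or the 2 brightest where fewer than 2 passed. List members named because they passed only when adjusted over the list alone were chosen after their values were seen, and so was the unnamed transcript in total RNA.

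Each of the 3 slides held the 4 arrays of 1 replicate number, so slide and replicate number are the same block, and every group sat at the same position on each slide. Same-numbered arrays deviated together from their group means within a fraction (r across genes of 0.307 to 0.460 for the total RNA pairs and 0.0851 to 0.473 for the polysomal pairs). Differently numbered pairs reached at most -0.0194 in total RNA and 0.161 in polysomal RNA. The latter lies above the 0.0851 of polysomal replicate 2, so these values do not bear out the pairing of that replicate. Across fractions the same-numbered correlations ran from -0.00 to 0.249. The numbers were read as pairing the arrays, because they mark a shared repeat and a shared slide, and a fit with the number as a block (6 residual degrees of freedom) was an alternative. The other alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the series matrix values, no filter or a filter on all 12 arrays, the mean of a gene's probes, only the arrays of the compared groups, eBayes with trend and robust options, array weights, a 2-fold minimum, and leaving out each array in turn.

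The procedure was tested on simulated data for 19207 genes with 200 changed. For the polysomal comparison it recovered 22.4% of changes of 0.5 on the log2 scale, 64.2% of changes of 1 and 95.5% of changes of 2. For total RNA the shares were 26.9%, 71.6% and 92.4%, for the interaction 0%, 55.2% and 83.3%, and for polysomal against total RNA 31.3%, 73.1% and 95.5%. Between 3.97% and 7.30% of the simulated calls were wrong. A simulated list of 40 genes shifted by 0.3 was called, and 0 of the unshifted lists were. Simulated genes varied independently of one another, with the same spread in every group and no replicate effect. The simulation therefore cannot show how often list tests call wrongly when genes are correlated, as with the preset correlation of 0.01. Nor does it give the shares recovered or wrong at the real spreads, which were wider in polysomal than in total RNA.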

Results

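RNA levels were measured in CHP134, an established neuroblastoma cell line driven by the MYCN oncogene, after 90 min with 5 µM CPX, which the labels describe as an iron chelator, or with vehicle. The series set out to describe the transcriptional and the translational response to the compound. Total RNA stood for the former, and RNA recovered from polysomes, the mRNAs loaded with several ribosomes, for the latter. Each of the 4 groups (vehicle total, CPX total, vehicle polysomal, CPX polysomal) held 3 arrays from 3 repeats of the experiment. Between 27997 and 30561 of the 43376 non-control spots on an array (64.5% to 70.5%) were well above background. Arrays of 1 group correlated at r of 0.987 to 0.997 across genes. The median SD of a gene within a group was 0.10 (log2) in vehicle total, 0.13 in CPX total, 0.19 in vehicle polysomal and 0.19 in CPX polysomal RNA. The number of arrays limits the precision: the median standard error of a CPX effect was 0.15 on the log2 scale and that of the interaction 0.21. Levels are log2 processed intensity relative to the array's 75th percentile, coordinates are those of the probe on GRCh37, and the place of probes in exons or untranslated regions was not analysed here.

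In total RNA, no gene with a symbol passed the threshold after 90 min of CPX, and 1 of 19251 genes did. That gene, an unnamed transcript probed at chromosome 6, 90067728 to 90067787 (THC2642650), fell by 0.91 ± 0.10 (log2, SE, n = 3 per group; limma adjusted p = 0.0392). It was lower with CPX in all 3 replicates (-0.78, -1.03 and -0.92), although only 1 of the 3 CPX total arrays measured it well above background and its value turned to 0.22 with normexp background. At an unadjusted p under 0.05 there were 821 genes (470 higher, 351 lower), where chance alone gives 963.

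HIF-induced genes, the set switched on by hypoxia-inducible factors, rose as a group in total RNA: 29 of the 37 measured members had values above 0 and the list's median change was 0.12 (camera adjusted p = 0.00136). The adjusted p was 0.374 with an estimated correlation. No member passed over all genes. Adjusted over the list alone, 5 of the 37 did. These were ANKRD37 (0.69 ± 0.13), the mTORC1 inhibitor DDIT4 (1.30 ± 0.32), the angiogenic factor VEGFA (0.69 ± 0.17) and the histone demethylase KDM3A (0.62 ± 0.18) above vehicle, and the sterol regulator INSIG2 (-0.39 ± 0.11) below it. The vasodilator peptide ADM had a value of 0.77 ± 0.31 (adjusted p = 1) and the lipid droplet protein HILPDA 0.20. For ADM the CPX total arrays (-2.94, -2.94 and -2.67) all lay above the vehicle total arrays (-3.58, -3.65 and -3.65). Its SE of 0.31 is pooled over all groups and takes in the wider CPX polysomal arrays (0.71, 0.11 and -0.96). The lack of a call for ADM is thus no evidence against a rise in total RNA.

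3 lists fell as groups in total RNA by camera with the preset correlation, each with an adjusted p of 4.83e-04. They were p53 targets (median -0.04, 19 of 24 below 0), heat shock proteins (median -0.04, 14 of 19 below 0) and replication-dependent histones (median -0.07, 36 of 47 below 0, and 0.02 with normexp background, which moved the median of all genes from 0.02 to 0.09). With an estimated correlation the adjusted p was 0.374 for p53 targets, 0.374 for heat shock proteins and 0.964 for histones. No member of the 3 lists passed over all genes. Adjusted over the list alone, the co-chaperone DNAJB1 (-0.65 ± 0.10), HSPA6 (-0.57 ± 0.16, but 0.42 with normexp background) and the inducible HSP70 gene HSPA1A (-0.87 ± 0.25) passed among 19 heat shock genes, and the translesion polymerase POLH (-0.44 ± 0.11) and PHLDA3 (-0.53 ± 0.14) among 24 p53 targets. The brightest members of the 3 lists lay near 0: HSPA8 at 0.00, HSPD1 at -0.02, FDXR at -0.01, BBC3 at -0.02, HIST1H1C at -0.07 and HIST1H3C at 0.06, where for HSPA8 1 of 4 probes had the opposite sign. Of the lists not called, immediate early genes came closest (camera adjusted p = 0.0758), with the transcription factor KLF6 at 0.43 ± 0.10 past the threshold adjusted over the list alone.

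None of the 10 genes with the smallest p in total RNA that have a symbol passed the threshold. The 5 above vehicle were LIMS3 (1.70 ± 0.24, adjusted p = 0.126), TTC32 (0.71), TMEM176A (0.72), the MAX-binding repressor MNT (0.52) and TARBP1 (0.51, adjusted p = 0.163). The 5 below vehicle were FBXL18 (-0.53, adjusted p = 0.126), DNAJB1 (adjusted p = 0.142), MIA (-1.11) and the zinc finger genes ZNF540 (-0.92) and ZFP14 (-0.61), the last 3 at an adjusted p of 0.152. With normexp background MIA (0.0105) and ZNF540 (0.13) turned sign. Genes of iron handling had small values: the transferrin receptor TFRC 0.12 ± 0.19, ferritin heavy chain FTH1 0.10 ± 0.18 (2 of 5 probes with the opposite sign) and ferritin light chain FTL 0.01 ± 0.24. MYCN stood at 0.10 ± 0.13, MYC at 0.62 ± 0.33 (1 of 2 probes with the opposite sign), the ribonucleotide reductase subunit RRM2 at 0.01, ATF4 at -0.02, DDIT3 at -0.42 ± 0.15 (adjusted p = 0.856) and CDKN1A at -0.12. BNIP3 (0.28), EGLN1 (0.22), SLC2A1 (0.21), NDRG1 (0.10), HIF1A (0.05), EGLN3 (0.04) and CA9 (-0.12) did not pass, nor did ODC1 (0.14), DHPS (0.04), DOHH (0.03) and EIF5A (-0.04). The count of 1 became 3 with the replicate as a block (THC2642650 and 2 unnamed probes) and 261 with array weights, and 0 without any 1 of vehicle total replicates 1, 2 and 3 and CPX total replicates 2 and 3. It was also 0 with normexp background, without the filter, with the filter on all 12 arrays, with trend and robust options, and with only the compared arrays. With quantile normalization, with the series matrix values and without CPX total replicate 1 the count was 1, but the gene was not THC2642650.

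In polysomal RNA, 6 genes rose after CPX and none fell, and 4 of the 6 are HIF-induced genes. ADM rose 12.3-fold (95% interval 7.59 to 19.9), DDIT4 5.34-fold (3.29 to 8.67), VEGFA 3.02-fold and ANKRD37 2.65-fold. These intervals use the spread pooled over all 12 arrays, which for a typical gene narrows them in polysomal RNA. The other 2 were CIART, a repressor within the circadian clock, which rose 1.98-fold, and the secreted proteoglycan TSKU, which rose 1.69-fold. Each of the 6 was higher with CPX in all 3 replicates. Over 17 alternatives ADM and ANKRD37 were called in 16, VEGFA in 12, CIART in 10, TSKU in 8 and DDIT4 in 6 (adjusted p up to 0.216). With only the polysomal arrays in the fit, none of the 6 was called (limma adjusted p = 0.156 for ADM and 0.0799 for ANKRD37). All 6 calls thus rest on a spread estimated together with the total RNA arrays.

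ADM, probed at chromosome 11, 10328780 to 10328839, went from a level of -3.67 ± 0.11 (SD, n = 3) in vehicle polysomal RNA to -0.05 ± 0.85 with CPX, a log2 change of 3.62 ± 0.31 (SE; limma adjusted p = 0.00293). Its changes per replicate were 4.48, 3.78 and 2.60. The SE and the interval above pool the spread of all groups and do not fully reflect the SD of 0.85 among its CPX polysomal arrays. ANKRD37 (chromosome 4, 186321293 to 186321352) went from -0.41 ± 0.16 to 1.00 ± 0.01, a change of 1.41 ± 0.13 (adjusted p = 0.00293). VEGFA (chromosome 6, 43746223 to 43746634) went from -3.01 ± 0.10 to -1.41 ± 0.19, a change of 1.60 ± 0.17 (adjusted p = 0.0114). DDIT4 (chromosome 10, 74035363 to 74035422) went from 3.70 ± 0.50 to 6.11 ± 0.25, a change of 2.42 ± 0.32 (adjusted p = 0.0391), with 2.13, 2.53 and 2.59 per replicate. CIART, which the array files call C1orf51 (chromosome 1, 150259057 to 150259116), changed by 0.99 ± 0.11 (adjusted p = 0.0167) and TSKU (chromosome 11, 76508863 to 76508922) by 0.76 ± 0.10 (adjusted p = 0.0311). With the replicate as a block, DDIT4 (adjusted p = 0.102) and TSKU (0.0581) were no longer called, and the dim probes of HRH1 (-3.19, 0.0206) and AGBL4 (-3.67, 0.0245) were. At an unadjusted p under 0.05 there were 1511 genes (684 higher, 827 lower) against 963 by chance.

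**Figure D1:**
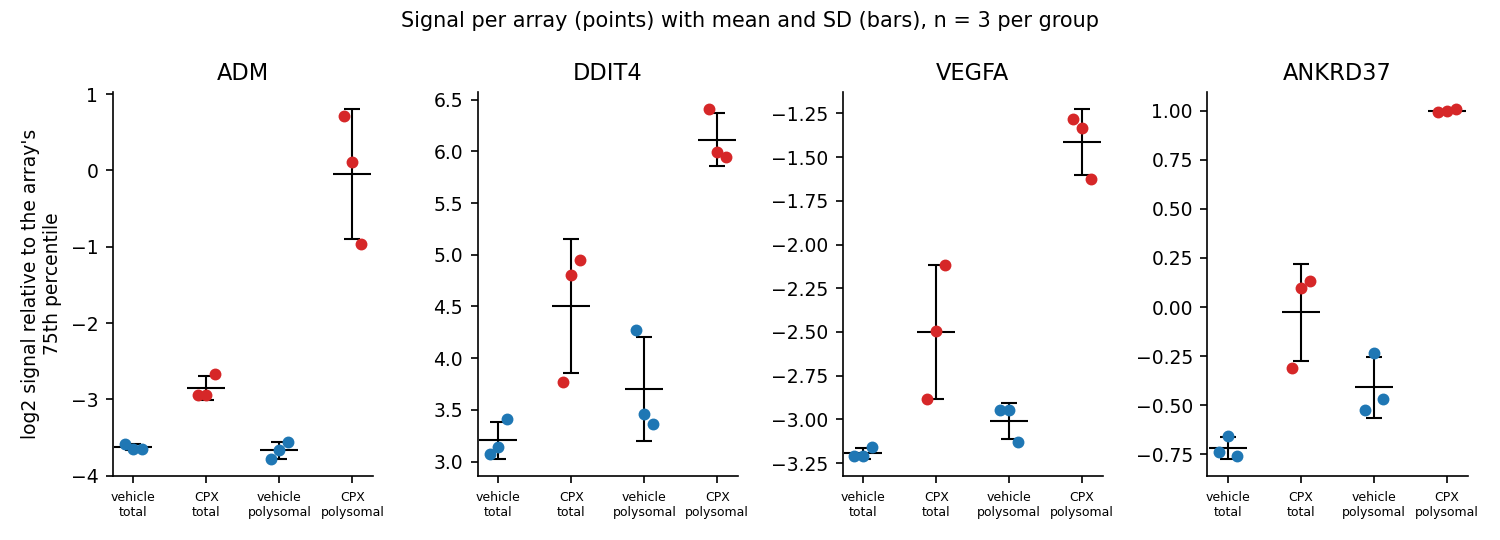
Level of ADM, DDIT4, VEGFA and ANKRD37 on each array (points; y axis, log2 signal relative to the array's 75th percentile) in the 4 groups, with the mean and SD of 3 arrays (black lines and bars). In polysomal RNA the CPX arrays lie above the vehicle arrays for all 4 genes.

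HIF-induced genes rose in polysomal RNA as a group. Of 37 measured members, 4 passed over all genes, 13 adjusted over the list alone, and 33 had values above 0, with a median change of 0.19 and a mean of 0.54 (camera adjusted p = 1.45e-11). Medians per replicate were 0.33, 0.26 and 0.23. This call held with an estimated correlation (adjusted p = 0.0205) and by fry (adjusted p = 0.00129). Besides the 4 genes above, those past the threshold adjusted over the list alone were the transcriptional repressor BHLHE40 (2.43 ± 0.69), the secreted glycoprotein STC2 (1.13 ± 0.23), KDM3A (1.10 ± 0.18), the glycogen-targeting subunit PPP1R3C (0.91 ± 0.23), the fucosyltransferase FUT11 (0.73 ± 0.10, adjusted p = 0.0568 over all genes), RAB20 (0.71 ± 0.21), HILPDA (0.63 ± 0.17), the glycolytic regulator PFKFB3 (0.60 ± 0.12) and the mitophagy receptor BNIP3 (0.59 ± 0.11). The other HIF-related genes named in advance did not pass: EGLN1 (0.41 ± 0.17), SLC2A1 (0.22, and 0.84 by its other, dimmer probe), EGLN3 (0.11), CA9 (0.04) and NDRG1 (0.04, and 1.56 by its other, dimmer probe). The factor's own subunit HIF1A stood at -0.45 ± 0.15 (adjusted p = 0.551).

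ER unfolded protein response genes fell in polysomal RNA as a group: 20 of 22 measured members had values below 0, with a median of -0.22 (camera adjusted p = 3.91e-09). The list holds chaperones and folding enzymes of the endoplasmic reticulum, and also degradation factors and regulators of the response. The call held with an estimated correlation (adjusted p = 0.00739) and by fry (adjusted p = 0.00133), and the median was -0.09, -0.28 and -0.26 in the 3 replicates. No member passed over all genes. Adjusted over the list alone, 4 did: the HSP70-type chaperone HSPA5, also called BiP (-0.96 ± 0.18), the degradation adaptor SEL1L (-0.82 ± 0.22), calnexin CANX (-0.49 ± 0.12) and the disulfide isomerase PDIA4 (-0.39 ± 0.12). The 2 brightest members, MANF (-0.10 ± 0.12) and SDF2L1 (-0.03 ± 0.15), did not.

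Heat shock proteins also fell as a group in polysomal RNA (median -0.30, 17 of 19 below 0, medians per replicate -0.49, -0.15 and -0.37; camera adjusted p = 2.36e-07). The adjusted p was 0.0746 with an estimated correlation and 0.0193 by fry. HSPA1A (-1.24 ± 0.25), CHORDC1 (-0.51 ± 0.13), BAG3 (-0.49 ± 0.14) and DNAJB1 (-0.47 ± 0.10) passed adjusted over the list alone and none did over all genes, while the constitutive HSPA8 (-0.30 ± 0.18, 1 of 4 probes with the opposite sign) and the mitochondrial HSPD1 (-0.04 ± 0.13) did not pass.

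4 more lists were called in polysomal RNA with the preset correlation only. Cytosolic ribosomal proteins (73 of 79 above 0, median 0.13) and nuclear-encoded OXPHOS subunits (66 of 75 above 0, median 0.13) rose, each with a camera adjusted p of 3.40e-04, and had adjusted p-values of 0.806 and 0.784 with an estimated correlation. Their medians were 0.43 and 0.40 in replicate 1, -0.39 and -0.16 in replicate 2, and 0.39 and 0.18 in replicate 3, so replicate 2 ran the other way. The medians over all arrays were 0.00569 and 0.0538 with quantile normalization and 0.0167 and 0.0567 with the series matrix values. Among them RPS15 stood at 0.11, RPS2 at 0.16 (2 of 6 probes with the opposite sign), NDUFS5 at 0.14 and UQCRH at 0.27, none of which passed. Ribosome biogenesis genes fell (26 of 35 below 0, median -0.10; camera adjusted p = 0.00105, adjusted p = 0.784 with an estimated correlation; medians per replicate -0.30, -0.0182 and -0.0271, and -0.0521 over all arrays with normexp), although the brightest of them, the nucleolar proteins FBL (0.10) and NPM1 (0.27), had values above 0 and did not pass. BCL2 family genes rose (15 of 19 above 0, median 0.14; camera adjusted p = 0.0156, adjusted p = 0.784 with an estimated correlation), and BNIP3 and the anti-apoptotic BCL2L1 (0.38 ± 0.10) passed adjusted over the list alone. Its medians per replicate were 0.38, -0.13 and 0.18, so replicate 2 ran the other way here too. MCL1 (-0.10, 1 of 3 probes with the opposite sign) and BBC3 (0.09) did not.

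**Figure D2:**
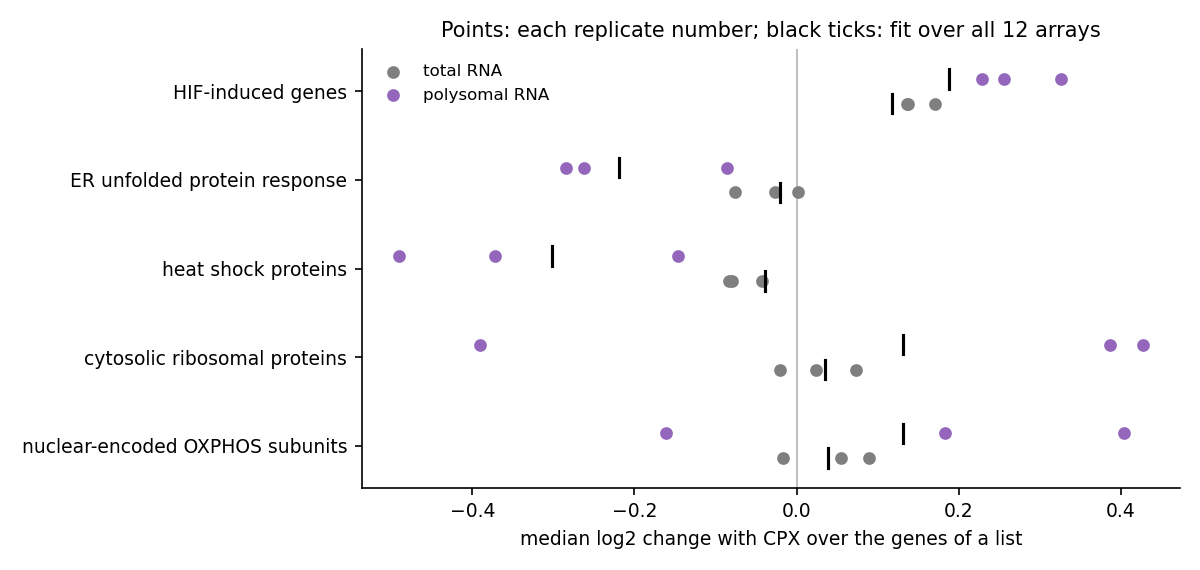
Median log2 change with CPX over the genes of 5 lists (x axis) in each replicate (points) and in the fit over all 12 arrays (black ticks), for total RNA (grey) and polysomal RNA (purple). In polysomal RNA the 3 replicates share 1 sign for HIF-induced genes, ER unfolded protein response genes and heat shock proteins, and replicate 2 stands apart for ribosomal proteins and OXPHOS subunits.

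The other lists were not called in polysomal RNA. Camera adjusted p-values were 0.0645 for G1/S and DNA replication (0.0405, called, with the replicate as a block, and 0.784 with an estimated correlation), 0.0668 for polyamine metabolism and eIF5A hydroxylation, 0.106 for nuclear or non-coding RNAs, 0.113 for ATF4 and integrated stress response, 0.132 for G2/M and 0.183 for iron- and oxoglutarate-dependent dioxygenases. They were 0.243 for p53 targets, 0.243 for immediate early genes, 0.304 for metallothioneins and zinc transporters, 0.373 for mesenchymal or Schwann-like cell markers, 0.376 for translation initiation factors and 0.376 for proteasome subunits. Iron uptake, storage and iron-sulfur genes, MYCN and MYC-family targets, cholesterol synthesis and adrenergic neuroblastoma identity each had 0.433, histones 0.439 (median 0.01 but mean -0.02), glycolysis and glucose uptake 0.487, other 5' TOP mRNAs 0.623 and NRF2 targets 0.880. None of the 13 mitochondrially encoded transcripts was measured. Single members passed adjusted over their list alone: the pyruvate dehydrogenase kinase PDK1 (1.01 ± 0.20) among 19 glycolysis genes, KDM3A among 40 dioxygenases and STC2 among 27 integrated stress response genes.

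Iron genes and regulators of growth did not pass in polysomal RNA. TFRC stood at -0.05 ± 0.19, FTH1 at -0.09 ± 0.18 (2 of 5 probes with the opposite sign), FTL at -0.05 ± 0.24 (1 of 3 probes with the opposite sign), MYCN at 0.25 ± 0.13, MYC at 0.09 ± 0.33, RRM2 at -0.13 ± 0.10, ATF4 at 0.17 ± 0.17, DDIT3 at -0.27 ± 0.15 and CDKN1A at 0.01. EIF5A, which carries the hypusine residue made by the iron enzyme DOHH, stood at 0.25 ± 0.14, DOHH at 0.03, DHPS at 0.14 and ODC1 at 0.17. The count of 6 was 10 without vehicle polysomal replicate 1, 3 without CPX polysomal replicate 1, 2 without replicate 2 of either polysomal group and 3 without vehicle polysomal replicate 3. It was 3 without the filter on dim probes, and with only the polysomal arrays in the fit it was 1, a gene that fell.

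The interaction asks whether CPX changed a gene's RNA on polysomes more than in the cell as a whole, the translational part of the response. No single gene passed (limma; 579 genes at an unadjusted p under 0.05, 963 by chance), but 2 lists stood out. HIF-induced genes rose more in polysomal than in total RNA, with a median difference of 0.16 and a mean of 0.36 (26 of 37 above 0; camera adjusted p = 6.11e-07), and the adjusted p was 0.0879 with an estimated correlation and 0.0791 by fry. ER unfolded protein response genes fell more in polysomal RNA, with a median difference of -0.22 (19 of 22 below 0; camera adjusted p = 1.67e-05). That call held with an estimated correlation (adjusted p = 0.0400) and not by fry (adjusted p = 0.0620).

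Among HIF-induced genes, 7 passed adjusted over the list alone in the interaction: ADM (2.85 ± 0.44, adjusted p = 0.452 over all genes), PPP1R3C (1.19 ± 0.32), VEGFA (0.90 ± 0.24), ANKRD37 (0.72 ± 0.18), FUT11 (0.65 ± 0.15), INSIG2 (0.58 ± 0.15) and PFKFB3 (0.57 ± 0.17). DDIT4 had 1.12 ± 0.45, KDM3A 0.48 ± 0.26, BNIP3 0.32, NDRG1 -0.06 (its other probe had the opposite sign, at 1.36), EGLN1 0.19, CA9 0.16 and HIF1A -0.50 ± 0.21, and no ER gene passed even over its list. Medians per replicate were 0.19, 0.19 and 0.10 for HIF-induced genes and -0.08, -0.29 and -0.26 for ER genes. Another 8 lists were called with the preset correlation and in none of them did the call hold with an estimated correlation, where adjusted p-values ran from 0.432 to 0.878. Cytosolic ribosomal proteins (camera adjusted p = 0.0158, its median turning from 0.10 to -0.00 under another scaling), OXPHOS subunits (0.0260), BCL2 family (0.0280) and polyamine metabolism genes (0.0293) rose more on polysomes. Ribosome biogenesis (0.0158), G2/M (0.0158), G1/S and DNA replication (0.0228) and integrated stress response genes (0.0280) fell more. With the replicate as a block, OXPHOS subunits (0.0519) and polyamine metabolism (0.0520) were no longer called and heat shock proteins were (0.0831 without it, 0.0375 with it, and 0.772 with an estimated correlation).

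**Figure D3:**
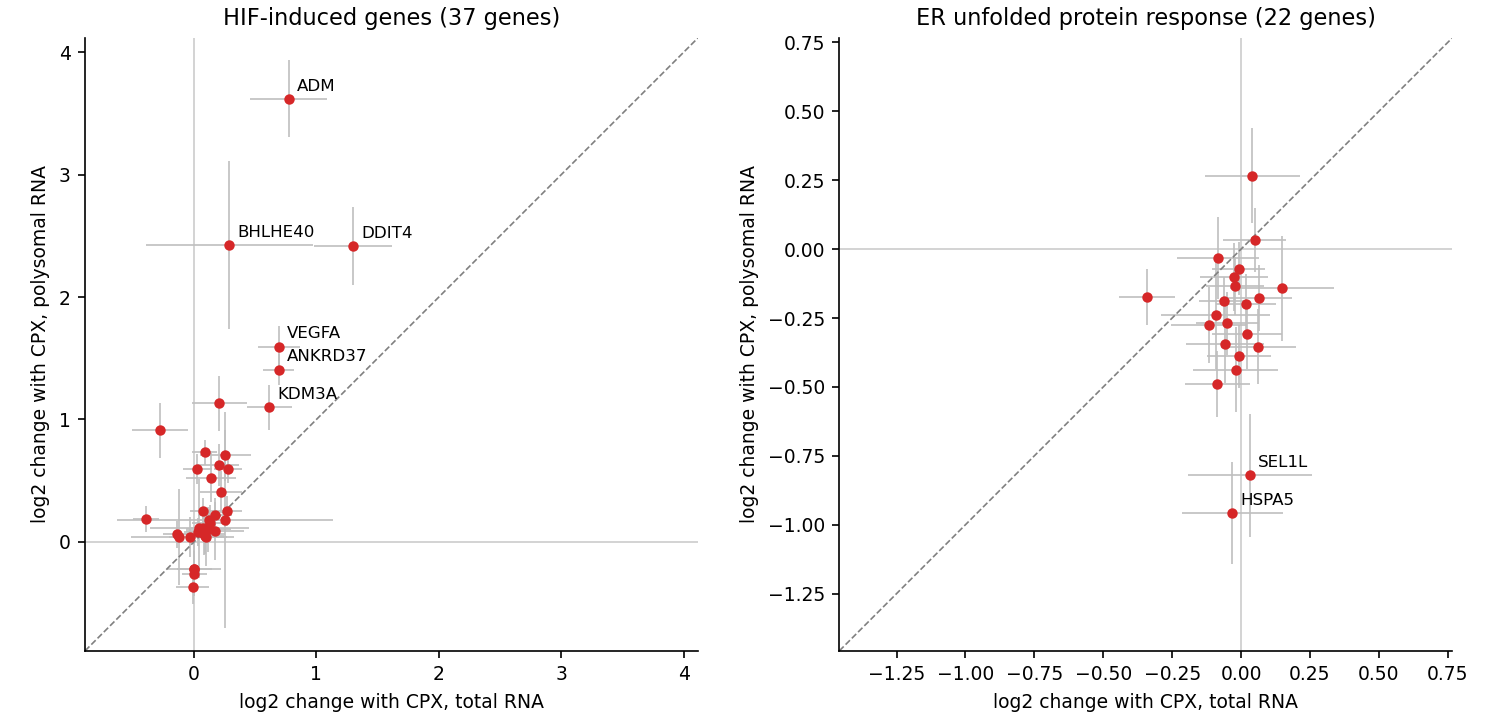
Log2 change with CPX in total RNA (x axis) and polysomal RNA (y axis) for each measured HIF-induced gene (37, left) and ER unfolded protein response gene (22, right), with bars of 1 SE and a dashed line of equal change. ADM lies at 0.77 and 3.62, HSPA5 at -0.03 and -0.96.

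The smallest interaction p belonged to TMEM176A, at -1.25 ± 0.16 (adjusted p = 0.245), and none of the genes with the smallest p passed. ADM, FUT11 and MMP24 (0.60) were the best measured of those above 0, while GPRC5D (3.29), PABPC3 (1.23), AGBL4, ABCA1 and GRPR (-1.39) rest on probes that are dim in at least 1 group. The remaining genes named in advance had interaction values with an adjusted p of 0.9995 or 1, among them MYC -0.53 ± 0.46 (1 of 2 probes with the opposite sign), EIF5A 0.28 ± 0.20, TFRC -0.17 ± 0.27, FTH1 -0.18 ± 0.26 (2 of 5 probes with the opposite sign), MYCN 0.14 ± 0.18 and ATF4 0.20 ± 0.23. Across the 19251 genes, CPX effects in total and polysomal RNA correlated with Pearson's r of 0.206 and Spearman's rho of 0.216, genes not being independent replicates, and 58.5% of genes had the same sign. Within single replicates r was 0.109, 0.0846 and 0.125. Of the 1511 polysomal genes with an unadjusted p under 0.05, 1045 (69.2%) had the same sign in total RNA, and 101 genes were nominally higher and 79 nominally lower in both, where independent lists would share 16.7 and 15.1. Without the filter on dim probes r was 0.0189, and without vehicle polysomal replicate 1 it was 0.131.

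In vehicle-treated cells, polysomal and total RNA differed in 6366 of the 19251 genes, 3552 higher and 2814 lower on polysomes (55.8% higher). Replication-dependent histone mRNAs were the most enriched list, with 41 of 47 higher on polysomes and a median log2 difference of 1.14 (camera adjusted p = 9.34e-23). Neither this call nor the other 6 in this comparison held with an estimated correlation (adjusted p of 0.576 for histones and heat shock proteins and 0.735 for the other 5), though by fry histones had 1.92e-04. OXPHOS subunits were also enriched (38 of 75 higher, 2 lower, median 0.38; adjusted p = 4.93e-07). Heat shock proteins (10 of 19 lower, 1 higher, median -0.41; adjusted p = 6.14e-04), ribosome biogenesis genes (17 of 35 lower, 2 higher, median -0.24; 0.00452), nuclear or non-coding RNAs (6 of 19 lower, median -0.44; 0.00452) and G2/M genes (13 of 32 lower, 5 higher, median -0.10; 0.0303) were depleted. Polyamine genes were enriched (7 of 16 higher, median 0.31; 0.0423), a call not made with the replicate as a block (0.0645).

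Among histones, HIST1H3B stood at 2.04 ± 0.15 (adjusted p = 1.60e-05), HIST1H3F at 1.96, HIST1H3E at 1.87 and HIST1H1B at 1.83. COX7B (1.05 ± 0.15), NDUFB11 (1.01), UQCRB (1.00) and ATP5D (0.97) led the OXPHOS subunits, and DHPS (0.56), SAT1 (0.55), SMS (0.47) and OAZ2 (0.45) the polyamine genes. HSPA1A (-1.99 ± 0.25), HSPA4L (-1.47), HSPH1 (-1.36) and HSP90AB1 (-0.90) were lower, as were the nucleolar factors RRP12 (-1.88 ± 0.25), UTP20 (-1.85), POLR1A (-1.63) and MYBBP1A (-1.29), and the mitotic genes TOP2A (-1.86 ± 0.19), CENPF (-1.28), CENPE (-1.24) and MKI67 (-1.15). The long non-coding RNAs KCNQ1OT1 (-2.36 ± 0.20), MALAT1 (-1.17), SNHG7 (-1.03) and NEAT1 (-0.97) were lower too, with list medians of -1.05, -0.11 and -0.21 in the 3 replicates. Ferritin mRNAs, which carry iron-responsive elements, were lower on polysomes in vehicle (FTL -1.29 ± 0.24, FTH1 -0.87 ± 0.18), as was ACO1 (-0.89), although the iron list as a whole was not called (3 higher, 7 lower of 24; adjusted p = 0.365).

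The largest single differences were on CCDC71 (2.74 ± 0.15, adjusted p = 3.68e-06), GEN1 (2.60 ± 0.11) and TAF5L (3.73 ± 0.52) above total RNA and on CD86 (-5.00 ± 0.29, adjusted p = 3.68e-06), LAT (-3.37 ± 0.16) and MAMDC4 (-3.21 ± 0.18) below it. Where 1 fraction was not well above background only a bound can be given: AGBL4 was at least 3.56-fold and WWC2-AS2, in the files C4orf38, at least 2.88-fold higher on polysomes, and LRRC2 was at least 3.85-fold and ZNF765 at least 1.64-fold lower. Fraction and extraction procedure cannot be told apart here, and agreement between different probes of a gene was not examined for this comparison. The count was 7128 with the replicate as a block (6235 shared), 4074 with normexp background, 10408 with array weights and 1039 with a 2-fold minimum.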

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

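The use of the replicate block (itself an alternative set in advance) against a batch, and the tests of the spike-in slopes, the array positions and the replicate medians of ribosomal and OXPHOS lists were chosen only after the result was seen, and leaving out single arrays or ADM in list tests was added after the data were seen, with what it should show set before its values were computed, as was the list of other ER genes. All results here came from the test of whether the CPX effect differs between polysomal and total RNA.

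HIF-induced genes rose more on polysomes than in total RNA (median difference 0.16, above 0 in 26 of 37 genes; camera adjusted p = 6.11e-07), a call lost with an estimated correlation (0.0879) and by fry (0.0791), with a range of 8.39e-13 to 0.0879 over the alternatives. The adjusted p was 5.15e-06 with the replicate (and slide) as a block. Each slide held all 4 groups, so a shift shared by a slide cancels in the difference, and the block could not show a batch as the cause. A single array or ADM alone as the source is argued against: the adjusted p was at most 0.000498 in the 12 fits that each left out 1 array, and 1.22e-05 without ADM. These 3 p-values are from camera with the preset correlation. The spike-in dose-response slopes of the total RNA arrays were 1.01 times those of the polysomal arrays, so the spike-ins show no compression there. Compression for the list's own probes, some of them dim, was not tested. Array position stays open, because each group sat at 1 position on every slide and the effect of position cannot be told apart from that of the group. Of 100 splits of the arrays, 5 gave a camera list p for the difference as small (2.26e-08 for the real split, 1.97e-11 for the smallest other). The 4 others all left the polysomal arrays as labelled, and 0 of the 93 splits that regrouped them gave a p as small. A split that leaves the polysomal arrays as labelled keeps their CPX effect and is no test against chance. The share of 5 in 100 therefore cannot decide on chance, which was not excluded. For the rise in polysomal RNA itself, 1 of 10 splits was as small (real p 5.38e-13, smallest other 3.14e-07). Those splits are too few for a share under 0.05. An effect of CPX itself stays open beside array position and chance and was not tested apart from them.

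ER unfolded protein response genes fell more on polysomes than in total RNA (median difference -0.22, below 0 in 19 of 22 genes; camera adjusted p = 1.67e-05). A loss of ER-bound polysomes in general would also lower the mRNAs of the translocon and glycosylation machinery. Yet these 33 genes had a median polysomal change of -0.018 ± 0.037 (SE over genes) against -0.22 for the ER unfolded protein response list. This argues against such a loss, although an SE over genes holds no variation between arrays. The fall in polysomal RNA kept an adjusted p of 1.75e-08 with the replicate as a block and of at most 4.88e-06 in the 12 fits that each left out 1 array (6.22e-11 to 0.00739 over the alternatives run). A shift shared by a slide cancels here too, so the block could not show a batch as the cause. The splits are too few for the polysomal fall (1 of 10 as small, real camera p 2.90e-10, smallest other 1.67e-04). For the difference between fractions, 7 of 100 splits were as small (real p 1.24e-06, smallest other 3.89e-09). All 6 others again kept the polysomal arrays as labelled, and 0 of 93 that regrouped them were as small. Those 6 keep the polysomal CPX effect, so this share cannot decide on chance, which was not excluded. An effect of CPX itself, array position and chance in the difference between fractions all stay open.

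Cytosolic ribosomal proteins (68 of 79 above 0; camera adjusted p = 0.0158) and OXPHOS subunits (60 of 75; 0.0260) rose more on polysomes. The 2 lists' lowest median in a replicate was -0.39 in polysomal RNA, in replicate 2, against 0.43 and 0.39 for ribosomal proteins in the others. With quantile normalization the median differences fell from 0.10 to -0.00142 and from 0.09 to 0.0413. The replicate medians go with variation between repeats of the fractionation as the source. The fall with quantile normalization is instead a dependence on the scaling, and these sources were not told apart. With an estimated correlation both calls were lost (adjusted p of 0.878 and 0.839, up to 0.912 by fry).

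The remaining lists are given with the camera adjusted p and that with an estimated correlation. Over the alternatives run for lists the highest lay between 0.831 and 0.944. Ribosome biogenesis fell more on polysomes (25 of 35 below 0; 0.0158 and 0.772), as did G2/M (22 of 32; 0.0158 and 0.772), G1/S and DNA replication (26 of 39; 0.0228 and 0.772; replicate 3 had a median of the other sign, 0.03) and ATF4 and integrated stress response (20 of 27; 0.0280 and 0.432). The BCL2 family (16 of 19 above 0; 0.0280 and 0.772) and polyamine metabolism and eIF5A hydroxylation (14 of 16; 0.0293 and 0.772) rose more, although replicate 2 had medians of -0.13 and -0.07.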

How the results depend on the processing

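The alternatives for the effect averaged over both fractions, and leaving out arrays for gene lists, were chosen only after the result was seen. HIF-induced genes and ER unfolded protein response genes in polysomal RNA stayed past the threshold in the same direction under every alternative run for lists. Their adjusted p-values by camera reached at most 0.0205 and 0.00739. List tests were not run with median centring, series matrix values, the filter on all 12 arrays, trend and robust options, array weights or only the compared groups. Of the 6 polysomal calls, ADM and ANKRD37 were called in 16 of 17 alternatives (adjusted p up to 0.156 and 0.0799), VEGFA in 12, CIART in 10, TSKU in 8 and DDIT4 in 6, all with log2 changes above 0. Among the named genes and the lists, the replicate block changed no call other than those given with the results.

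In total RNA the gene called was another with quantile normalization and with series matrix values. The count of 1 was 3 with the replicate block and 261 with array weights. It was 0 with normexp background, no filter on dim probes, the filter on all 12 arrays, trend and robust options, only the compared groups, or a 2-fold minimum. In polysomal RNA the count of 6 was 3 with no filter and 1, not among the 6, with only the compared groups. The block left it at 6, of which 4 were shared. The interaction had 2 with array weights and 0 otherwise among the alternatives that keep all arrays. Polysomal against total RNA gave 4074 with normexp, 10408 with array weights and 1039 with a 2-fold minimum. The averaged effect gave 11, 9, 61 and 9 with normexp, no filter, array weights and a 2-fold minimum. The correlation of CPX effects between fractions, 0.206, was 0.269 with normexp, 0.0189 with no filter, 0.248 with the filter on all 12 arrays and 0.138 with array weights. A 2-fold minimum lowers counts by construction. For the other changes the cause was not tested.

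Signs turned for some named genes, with an adjusted p of at least 0.696 there. With normexp, MIA (0.0105), ZNF540 (0.13), CA9 (0.31), HSPA6 (0.42) and THC2642650 (0.22, and 0.0390 averaged over fractions) in total RNA, BX100717 averaged (0.23) and PABPC3 in the interaction (-0.35) did. In polysomal RNA, NDUFS5 turned to -0.0167 with quantile normalization, -0.0167 with series matrix values and -0.0529 with array weights, FBL to -0.0384, -0.0267 and -0.0126 with the same 3, ATF4 to -0.0537 with array weights and RPS2 to -0.0503 with the mean of probes, which also put NDRG1 at 0.65 in the interaction. For lists, heat shock proteins in polysomal RNA had 0.0746 with an estimated correlation. In the interaction HIF-induced genes had 0.0879 with an estimated correlation and 0.0791 by fry, and ER unfolded protein response genes 0.0620 by fry. There, relative to the other genes, ribosomal proteins turned down with quantile normalization (0.787) and ribosome biogenesis up with normexp (0.944), where its own median stayed below 0 (-0.08). The cause was not tested. The median of all genes moved by over 0.1 with normexp in the interaction (from 0.01 to -0.10).

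Leaving out 1 array gave 0 to 1 genes in total RNA and 2 to 10 in polysomal RNA. The interaction gave 0 to 1 (1 without vehicle polysomal replicate 1 or CPX polysomal replicate 3), and polysomal against total RNA 4466 to 7070. The averaged effect gave 5 to 26, with 5 without vehicle total replicate 2, 8 without replicate 3 of either total group, 9 without vehicle total replicate 1, and 11 to 15 without CPX total replicates 1 or 2, CPX polysomal replicates 1 or 2 or vehicle polysomal replicates 2 or 3. The correlation ran from 0.131 to 0.215. Signs changed within CA9 (-0.58 to 0.46) and EIF5A (-0.13 to 0.11) in total RNA, CA9 in the interaction (-0.42 to 0.62), and, in polysomal RNA, TFRC (-0.24 to 0.14), FTL (-0.35 to 0.20), EGLN3 (-0.32 to 0.58), MYC (-0.28 to 0.41), ATF4 (-0.0193 to 0.33) and UQCRH (-0.00171 to 0.42). Where an arm kept 2 arrays, the fit assumed the spread of the other groups. Highest adjusted p-values were 2.32e-06 for HIF-induced genes and 8.71e-05 for heat shock proteins in polysomal RNA, and 0.00116 for ER genes in the interaction. For the other called lists, alternatives that keep all arrays kept the call in 99 values, lost it in 61 and turned the sign in 2. Among 3942 gene values under alternatives, 120 changed sign by less than 1 SE. Signal over background limits dim genes: between 64.5% and 70.5% of spots were well above it.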

Other observations

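The effect of CPX averaged over both RNA fractions and its splits were chosen only after the result was seen, and the tests of zinc finger and clock genes were prompted by results for single genes, with what they should show set before their values were computed. Taking the mean of the CPX effects in total and polysomal RNA sets 6 arrays against 6. By their replicate numbers these come from 3 repeats measured in both fractions, not from 6 independent experiments. The main fit nevertheless treated all 12 arrays as independent. In that fit 23 genes passed (15 higher and 8 lower by limma, with 1564 at an unadjusted p under 0.05), all with the same sign in both fractions. They include the 6 genes called in polysomal RNA and the 1 called in total RNA. Of the 17 with a symbol, 5 are HIF-induced: ADM (2.20 ± 0.22), DDIT4 (1.86 ± 0.22), VEGFA (1.15 ± 0.12), ANKRD37 (1.05 ± 0.09) and the histone demethylase KDM3A (0.86 ± 0.13, adjusted p = 0.0423). CIART (0.72), TSKU (0.60), TTC32 (0.67), LIMS3 (1.28), CBX3P2 (1.00), C6orf58 (0.52) and the transcription factor SP2 (0.44) were also higher. The co-chaperone DNAJB1 (-0.56 ± 0.07, adjusted p = 0.0194), the oxytocin receptor OXTR (-0.55 ± 0.08), MIA (-1.09 ± 0.13), THAP2 (-0.67) and FBXL18 (-0.42) were lower, and the other 6 were unnamed transcripts. The count was 11 with normexp, 9 with no filter, 9 with a 2-fold minimum and 61 with array weights, and with normexp 2 of the 8 lower genes, THC2642650 (0.0390) and BX100717 (0.23), turned sign. Leaving out 1 array gave 5 to 26 genes, 5 without vehicle total replicate 2, 8 without replicate 3 of either total group, 9 without vehicle total replicate 1 and 11 to 15 without 6 others. With the replicate as a block 31 genes passed, 20 of them shared, and KDM3A (adjusted p = 0.0608), SP2 (0.0668) and 1 unnamed transcript (0.0563) did not, which leaves 4 HIF-induced genes of the 5. Of 100 splits 1, the real one, gave as many as 23 genes, and the highest of the others gave 2, but this effect was chosen after the data were seen, so that count is no independent test against chance.

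Zinc finger genes stood among those with the smallest p for a fall in total RNA (ZNF540 and ZFP14). As a class, 449 genes named ZNF or ZFP had a median change of -0.03 in total RNA against 0.02 for all genes, 259 of them were below 0, and 0 passed singly (61 at an unadjusted p under 0.05). Camera gave an unadjusted p of 5.75e-04, and of 0.0123 with an estimated correlation, so a small shared fall may be present in total RNA, while the median in polysomal RNA was 0.05 against 0.03 for all genes (p = 0.133), and the difference between fractions was not tested. Other scalings were not run for this class.

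CIART is a clock gene, and a rise of other clock genes with it was tested on 13 measured genes of a list of 15 that left out CIART and also BHLHE40, a clock repressor that stands among the HIF-induced genes and had a polysomal value of 2.43 ± 0.69. Their median polysomal change was -0.00 ± 0.05 (SE over genes, without variation between arrays) against 0.99 for CIART. Camera with an estimated correlation gave p = 0.999, so no rise of these 13 as a set was seen, which says nothing of BHLHE40.

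Other splits of the arrays were counted for each number of genes. In total RNA the real split gave 1 gene and the highest other 0 (1 of 10 splits as large), and in polysomal against total RNA 6366 against 0 (1 of 10). In polysomal RNA it gave 6 and the highest other 7 (2 of 10). With 10 splits each, these are too few for a share under 0.05. The split with 7 grouped CPX polysomal replicates 1 and 2 with vehicle polysomal replicate 1. It had 3933 genes at an unadjusted p under 0.05 against 1511 for the real split, which points to a structure of the polysomal arrays apart from CPX. It also sets both replicate 1 arrays against both replicate 3 arrays. Deviations from the group means correlated at 0.473 within replicate 1 and 0.418 within replicate 3, and at -0.419 and -0.409 between them. The splits were run without the replicate block. In these 3 comparisons the other splits that parted all replicate pairs had at most 0 genes. For the interaction the real split gave 0 genes (limma, 579 at an unadjusted p under 0.05), so all 100 splits were as large. The highest gave 23, and it is the split that exchanges all labels within 1 fraction and so tests the summed CPX effect.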
